A study of Mus musculus with 8 samples.

How the data were processed

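RNA from pancreatic islets of male C57Bl/6 wild-type and Irs2-/- mice, untreated or given sodium tungstate in the drinking water, was measured on 8 Affymetrix arrays, 2 for each of 4 groups. Per the submitters' processing notes, total RNA was extracted with an RNeasy kit and labelled with biotin, and the signals were summarised with RMA from the affy package in R 2.7.0. The deposited values are log2 expression per probe set, with a column for each array, as the authors made them, and all of its columns were used. Raw array files, scan dates and batches were not used here or are not given in the sources used here. Of 45037 probe sets besides 64 controls, 34945 name a single gene, 932 several and 9160 none in the probe annotation used. Gene names were compared with a RefSeq table, where 34741 were matched by gene number and 0 changed.

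Each of 18193 genes was represented by its probe set with the highest mean over the 8 arrays, and genes whose mean lay under the 40th percentile of the probe sets (log2 5.27) were left out of the tests (4824 genes), which left 13369. This filter uses no group labels. The 4 groups were fitted with a mean each in limma 3.58.1 (R 4.3.3; the data.table package, version 1.17.8) with empirical Bayes moderation, on 4 residual and 3.89 prior degrees of freedom, and p-values were adjusted by Benjamini and Hochberg within each of 8 contrasts, with a threshold of 0.05. The contrasts were the genotypes in untreated and in treated mice, tungstate in each genotype, treated Irs2-/- against untreated wild-type islets, the interaction, and the averages over treatment and over genotype. The median standard error of a difference between 2 groups was 0.14 (log2), and 0.20 for the interaction.

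Of 30 gene lists written by hand, 28 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The mean, the median and the direction of the test differed in sign for 1, 2, 7, 4, 2, 3, 1 and 6 lists (genotype untreated, tungstate in Irs2-/-, tungstate in wild type, genotype treated, treated Irs2-/- against untreated wild type, interaction, genotype averaged, tungstate averaged), each of them a list that did not pass. The members past the gene test were also counted after adjustment over the list alone. Some genes are in more than 1 list, such as Hk2 under dedifferentiation and glycolysis and Cdkn1a under apoptosis. Lists, contrasts, tests, thresholds and the rule for naming genes were chosen before the data were examined.

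Genes were named by this rule: Irs2 first. For each contrast, the rule then takes up to 10 genes higher and 10 lower with the largest log2 difference among those past the threshold whose arrays do not overlap between groups. Fewer than 5 are filled up with genes at an unadjusted p under 0.01, the up to 4 members of each list with the smallest p are added, and 26 fixed genes, of which 23 have a single-gene probe set. Not every gene the rule names is printed. Outside the rule, and chosen after their values were seen, are Gast and Cxcl9 for tungstate in wild-type islets, and Tac1, Cartpt, Grp, Pdyn, Nmb and Mfap3l for the genotypes in untreated mice and for tungstate in Irs2-/- islets.

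The reversal of genotype differences was measured as Pearson's r and covariance across genes and set against 100 simulated data sets. Alternatives tried were no filter and the 60th percentile, a variance trend with robust moderation, only the arrays compared, the replicate number as a block, array weights, median centring, quantile normalization, the mean of a gene's probe sets, all probe sets, the acinar marker level as a covariate, an adjusted p under 0.1, a change of at least 2-fold, an estimated correlation for lists, and leaving out each array in turn. Leaving out 2 arrays with outlying marker levels was added after seeing the data. Counts given with all probe sets are of probe sets and not of genes. The probe sets tested there include 23204 that name a single gene, against 13369 genes, so the counts are not alike. The workflow was tested on simulated data with 200 of 13369 genes changed, in 20 simulations: at a log2 change of 1 it recovered 75% of them for the genotype contrast and 74.6% for tungstate in Irs2-/- islets, and at 2 it recovered 97.8% and 97.85%. Of its calls 5.46% and 4.97% were false. A shifted list was found in 20 of 20 simulations, and 1 and 0 of 400 lists with no shift were called. The simulated noise was independent between genes and alike in all groups. These rates therefore do not cover lists whose genes vary together, or groups of unequal spread.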

Results

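Gene expression was measured in pancreatic islets of male C57Bl/6 mice that were either wild type or lacked insulin receptor substrate 2 (Irs2-/-). Irs2 is an adaptor protein that carries signals from the insulin and IGF-1 receptors, and mice without it are used as a model of diabetes with failing beta cells. Sodium tungstate, a salt studied as an oral glucose-lowering compound, was given in the drinking water for 21 days, from 10 to 13 weeks of age, and untreated mice drank plain distilled water. The concentration is written as 2 mg/ml in the description of the design and as 2 mg/dl in the labels of the samples, so the dose is not settled here. Each of the 4 groups (wild type or Irs2-/-, untreated or treated) held 2 oligonucleotide arrays from samples described as independent. Whether a sample was 1 mouse or a pool is not given in the sources used here, so the p-values measure the spread between these samples. Values are log2 expression of 45037 probe sets per array besides the controls. The number of arrays limits the precision: the median standard error (SE) of a difference between 2 groups was 0.14 on the log2 scale. Differences of single genes are given below as log2 ± SE over 2 arrays per group. This SE uses a spread pooled over all 4 groups and moderated with that of other genes. It is therefore not the spread between the arrays of the groups compared, which may be larger or smaller.

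The targeted gene followed the labels on all 8 arrays. Irs2, measured by 1 probe set, read 7.91 and 7.73 on the untreated and 7.89 and 7.61 on the treated wild-type arrays, against 4.54 and 4.89 on the untreated and 4.78 and 4.86 on the treated Irs2-/- arrays. The level without Irs2 lay below 5.27, the mean under which probe sets were left out of the tests. The position of this probe set relative to the deleted part of the gene is not given in the sources used here.

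The first principal component of the 13369 tested genes held 61.1% of their variance and ordered the groups. The wild-type arrays lay between -29.8 and -15.7 on it, the treated Irs2-/- arrays at 12.9 and 2.7, and the untreated Irs2-/- arrays at 46.3 and 34.96. Islet preparations carry some exocrine tissue, and the mean level of the acinar marker list, digestive enzymes made by exocrine cells, varied within groups. It was 8.39 and 11.39 on the untreated wild-type arrays, 9.82 and 9.79 on the treated wild-type arrays, 10.93 and 11.84 on the untreated Irs2-/- arrays, and 10.70 and 11.49 on the treated Irs2-/- arrays. The 18S ribosomal control probe sets read 10.84 ± 0.30 (SD, n = 2) in untreated Irs2-/- islets, below the 12.22 ± 0.67 of untreated wild-type, the 12.26 ± 0.45 of treated wild-type and the 11.52 ± 0.56 of treated Irs2-/- islets. The difference between 3' and 5' control probe sets was lowest there as well, for Gapdh (0.39 ± 0.03, against 0.49 to 0.52 in the other groups) and for actin (0.83 ± 0.15, against 1.01 to 1.08). On all of these measures both untreated Irs2-/- arrays lay below every other array, though the nearest lay close. 18S read 11.05 and 10.63 there, against 11.12 for treated Irs2-/- replicate 2. The Gapdh difference was 0.415 and 0.367, against 0.423 for the same treated array. The actin difference was 0.73 and 0.94, against 0.96 for untreated wild-type replicate 2.

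**Figure D1:**
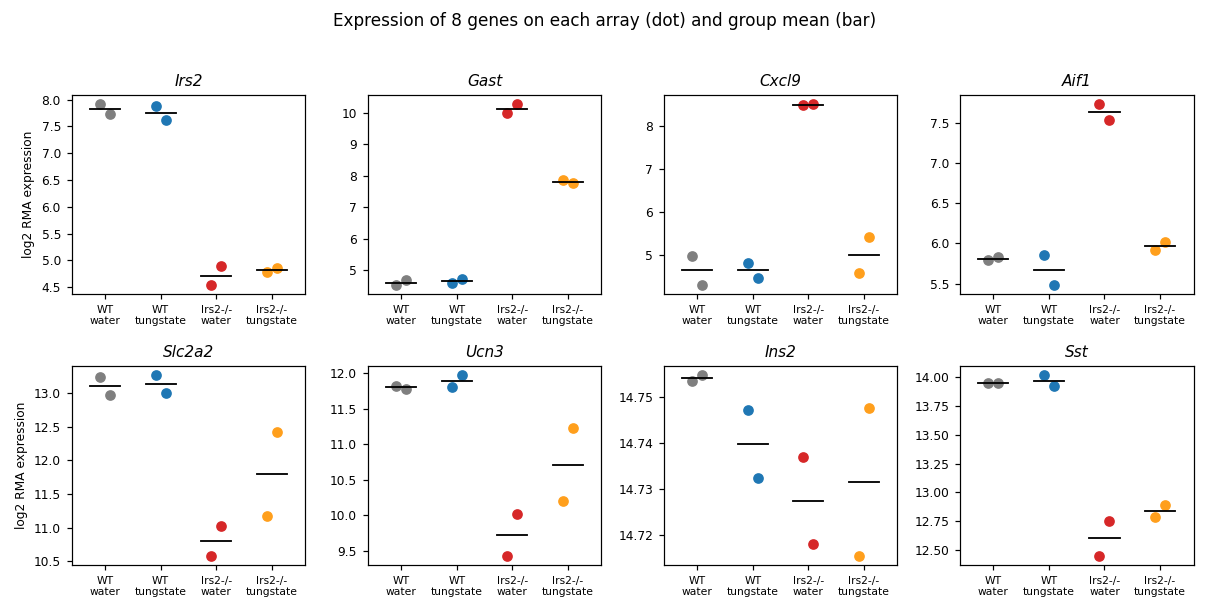
Log2 RMA expression of 8 genes on each array (dots) with the group mean (bar), for wild-type and Irs2-/- islets on water or tungstate. Gast and Cxcl9 are high in untreated Irs2-/- islets and lower after tungstate, Slc2a2 and Ucn3 are low in Irs2-/- islets, and the Ins2 axis spans less than 0.05.

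The comparison of untreated Irs2-/- with untreated wild-type islets asked what loss of Irs2 does to islet gene expression. Genes with which beta cells sense glucose and release insulin were lower without Irs2. Slc2a2, which encodes the glucose transporter GLUT2, was 4.94-fold lower (-2.30 ± 0.36, limma adjusted p = 0.00817). Ucn3, a peptide of mature beta cells, was 4.21-fold lower (-2.07 ± 0.32, limma adjusted p = 0.00743), and the taste-receptor channel gene Trpm5 was 5.96-fold lower (-2.58 ± 0.32, adjusted p = 0.00338). Also lower were the zinc transporter gene Slc30a8 (-1.50 ± 0.22), Sytl4, which acts in granule docking (-2.03 ± 0.31), the incretin receptor gene Glp1r (-1.78 ± 0.34) and the transcription factor genes Nkx6-1 (-1.21 ± 0.19) and Pdx1 (-0.74 ± 0.16). Of the 25 tested members of the list of beta cell identity and insulin secretion, 14 fell and 1 rose (15 and 1 when adjusted over the list alone). The list mean was -0.80 (limma camera adjusted p = 3.91e-06, adjusted p = 0.452 with an estimated correlation). Insulin itself did not pass the test: Ins2 was -0.03 ± 0.10 (limma adjusted p = 0.884), at 14.75 and 14.73, the highest value of each array, where a change may go unseen. Ins1 and Mafa have no probe set naming a single gene and were not analysed here. Gcg, glucagon of alpha cells, was -0.13 ± 0.12 (limma adjusted p = 0.498), while Sst, somatostatin of delta cells, fell by 1.35 ± 0.13 (limma adjusted p = 0.00181). Among 9 tested markers of other islet endocrine cells 2 fell, Sst and Hhex (-0.60 ± 0.15; 3 fell and 1 rose over the list alone), and the list did not pass (mean -0.22, limma camera adjusted p = 0.077, adjusted p = 0.576 with an estimated correlation).

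Gast, the hormone gastrin, read 4.61 ± 0.11 (SD) in wild-type and 10.13 ± 0.18 in untreated Irs2-/- islets (difference 5.52 ± 0.13, limma adjusted p = 2.03e-06). Csn3, a casein, was higher by 5.69 ± 0.39 (limma adjusted p = 0.000627). The other genes of the top 10 were the trypsinogen gene Prss3 (5.80 ± 1.54), the immunoglobulin gene Iglv1 (5.17 ± 1.27), Cidea (4.62 ± 0.56), 6330403K07Rik (4.25 ± 0.41) and Sorcs1 (4.22 ± 0.41). Then came the prostaglandin receptor gene Ptger3 (4.19 ± 0.39), the chemokine gene Cxcl9 (3.86 ± 0.30) and the amino acid transporter gene Slc38a5 (3.75 ± 0.37). In wild-type islets Gast, Csn3, Cidea, Sorcs1, Ptger3 and Cxcl9 read below 5.27, so their differences are not exact measures of size. Prss3 and Iglv1 had the largest SE of the top 10. Prss3 is a gene of exocrine cells, and the acinar level was 8.39 and 11.39 on the untreated wild-type arrays. Its difference was not separated from a difference in exocrine tissue. Besides Irs2 (-3.10 ± 0.16) and Trpm5, the lowest were Gad1, which makes the transmitter GABA (-3.32 ± 0.58), Cox6a2 (-3.13 ± 0.65), Dpp10 (-2.59 ± 0.29), Cttnbp2 (-2.57 ± 0.36), T2 (-2.50 ± 0.33), Mcoln3 (-2.40 ± 0.41), Plut (-2.38 ± 0.59) and 4931431B13Rik (-2.36 ± 0.23). In the list of genes of dedifferentiated beta cells and genes normally silenced there, 8 of 15 rose and 0 fell (10 and 0 when adjusted over the list alone). Beside Gast they included Aldh1a3 (2.95 ± 0.55), the hexokinase gene Hk2 (0.73 ± 0.11) and Fbp2 (1.59 ± 0.26). The list mean was 1.37 (limma camera adjusted p = 3.91e-06, adjusted p = 0.252 with an estimated correlation). Whole islets were measured, and markers of immune and other cells were higher on the same arrays. Whether beta cells or other cells carried these genes was not told apart.

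Genes of immune cells were higher without Irs2. All 18 tested macrophage and antigen presentation markers were higher, 16 of them past the test (18 when adjusted over the list alone). They included Aif1 (1.82 ± 0.15, limma adjusted p = 0.00103), the complement gene C1qc (1.61 ± 0.13), the lysosomal marker Cd68 (1.82 ± 0.18) and Tyrobp (1.58 ± 0.17). Their mean difference was 1.54 (limma camera adjusted p = 2.5e-13, adjusted p = 0.252 with an estimated correlation). Of 13 lymphocyte markers 4 rose (9 over the list alone), including the T cell receptor subunits Cd3d (2.09 ± 0.38) and Cd3g (2.64 ± 0.52) and the adhesion gene Cd2 (2.34 ± 0.51). The list mean was 1.84 (limma camera adjusted p = 5.08e-05, adjusted p = 0.452 with an estimated correlation). Among cytokines and NF-kB targets 5 of 18 rose (7 over the list alone, where 1 fell), led by the acute-phase gene Saa3 (3.45 ± 0.37) and the chemokine gene Ccl5 (3.35 ± 0.36). Of the interferon response genes 6 of 18 rose (7 over the list alone), such as the immunoproteasome gene Psmb8 (1.40 ± 0.23) and Gbp2 (2.16 ± 0.39). Both lists passed (limma camera adjusted p = 0.000956 and 0.000977, adjusted p = 0.507 with an estimated correlation for each). The lymphocyte mean was 1.09 without untreated wild-type replicate 2, and the inflammatory mean of 0.94 was 0.44 and 1.43 without untreated Irs2-/- replicates 1 and 2.

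Markers of other tissue moved with the genotype too. The 22 acinar markers were all higher, with a mean of 1.50, but only Rbpjl passed (0.62 ± 0.16; 0 over the list alone), and the 5 Reg genes, secreted by stressed acinar cells, averaged 2.34 with 0 past limma's test (0 over the list alone). Endothelial markers (3 of 14 rose, such as Ramp2 at 1.69 ± 0.20; 5 over the list alone) were higher as a list. So were fibroblast and stellate cell markers (2 of 19 rose, such as Pdgfrb at 0.90 ± 0.24, and Col6a3 fell by 0.90 ± 0.23; 11 and 1 over the list alone) and duct markers (3 of 8 rose, such as the keratin gene Krt7 at 0.67 ± 0.16; 4 over the list alone). The limma camera adjusted p was 0.000489 for acinar, 0.0496 for Reg, 0.00103 for endothelial, 0.00039 for fibroblast and 0.0126 for duct genes. With an estimated correlation the adjusted p was 0.524, 0.512, 0.507, 0.507 and 0.512 in the same order. With the SE of the array means the list means were 1.50 ± 1.14, 2.34 ± 1.34, 0.45 ± 0.13, 0.77 ± 0.39 and 0.47 ± 0.22, again in that order. Without untreated wild-type replicate 1, the array with the lowest acinar level, the acinar mean was -0.0038 and the Reg mean 0.67, and both calls ended, while without replicate 2 of that group they were 2.99 and 4.02. The fibroblast mean of 0.77 was 1.24 and 0.30 without the same arrays. With the acinar level as a covariate the Reg mean was 0.77 ± 0.82 (SE of the array means) and its call ended. The duct call ended without the 2 arrays with outlying marker levels (untreated replicate 1 of each genotype; mean 0.48, against 0.47). The Reg call also ended without untreated Irs2-/- replicate 2 (mean 1.52) and without either treated Irs2-/- array (adjusted p = 0.0509 with limma's camera, at the same mean of 2.34). Of 3 tested Schwann cell markers 0 passed limma's test (1 over the list alone), and 0 red blood cell markers could be tested.

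Proliferation, lipid synthesis and signalling genes differed as well. Cell cycle genes were higher as a list (mean 0.64, limma camera adjusted p = 5.08e-05, adjusted p = 0.512 with an estimated correlation). Of 31 genes 4 rose, such as the nucleotide reductase gene Rrm2 (1.67 ± 0.24) and the replication gene Mcm5 (1.54 ± 0.28), and Ccnd2, the cyclin D2 of beta cells, fell by 0.86 ± 0.11 (16 and 2 over the list alone). Whether the cell cycle genes came from beta cells, immune cells or others was not told apart. Cholesterol and fatty acid synthesis genes were lower (mean -0.42, limma camera adjusted p = 5.08e-05, adjusted p = 0.252 with an estimated correlation), with 10 of 21 past the test (13 over the list alone, where 1 rose). Among these 10 were the desaturase gene Scd2 (-1.58 ± 0.11) and the sterol genes Msmo1 (-1.02 ± 0.15), Insig1 (-1.17 ± 0.18) and Idi1 (-0.93 ± 0.15). The ERK feedback phosphatase genes Dusp6 and Dusp4 rose by 2.24 ± 0.20 and 1.78 ± 0.22, 2 of 4 of 23 immediate early and ERK feedback genes that did (5 over the list alone). In the insulin and IGF signalling list, the loss of Irs2 itself included, 3 of 20 fell and Igf1 rose by 1.19 ± 0.27 (4 and 1 over the list alone). That loss lowers the list mean by design, and the list was not tested without Irs2. Among islet amino acid and serotonin genes 5 of 9 fell, such as the transporter gene Slc7a2 (-1.06 ± 0.16) and Ddc (-1.08 ± 0.18), and 1 rose, with the same counts over the list alone. Oxidative phosphorylation and ribosomal protein genes were slightly higher, with 3 of 43 (3 over the list alone; Uqcrh 0.87 ± 0.18) and 3 of 31 (0 over the list alone; Rps3 0.48 ± 0.12) past the test. The limma camera adjusted p for these 5 lists, in the order named, was 0.00508, 0.0143, 0.0192, 0.00191 and 2.78e-05, and the adjusted p was 0.512, 0.452, 0.411, 0.524 and 0.507 with an estimated correlation. With the SE of the array means their means were 0.38 ± 0.49, -0.30 ± 0.09, -0.29 ± 0.09, 0.18 ± 0.09 and 0.26 ± 0.07. The immediate early list had a mean of 0.38, which turned to -0.27 without untreated Irs2-/- replicate 1, and without replicate 2 of that group the calls of the insulin and IGF list (mean -0.25, against -0.30) and of oxidative phosphorylation (0.076, against 0.18) ended. Without untreated Irs2-/- replicates 1 and 2 the cell cycle mean was 0.31 and 0.96. The immediate early mean was 1.03 without replicate 2, and the oxidative phosphorylation mean 0.29 without replicate 1. With the acinar covariate the insulin and IGF (-0.20) and oxidative phosphorylation (0.14) calls ended. With no filter on the mean the amino acid and serotonin call ended at -0.018, against -0.29. Without the 2 arrays with outlying marker levels the immediate early mean was -0.17.

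Stress, metal and fuel-use lists did not pass the list test in this comparison, though members did. The zinc-binding metallothionein genes Mt1 and Mt2 fell by 1.29 ± 0.20 and 1.46 ± 0.25 while Mt3 rose by 0.79 ± 0.15 (3 of 9 down and 1 up; 4 and 1 over the list alone). In the unfolded protein response list 4 of 28 rose and 1 fell (6 and 1 over the list alone), with Edem1 at 1.49 ± 0.17 and Creld2 at 1.32 ± 0.23. The stress genes Ddit3 (0.13 ± 0.35), Hspa5 (0.20 ± 0.22) and Trib3 (-0.71 ± 0.31) did not pass. The glycolytic regulators Pfkfb3 (2.19 ± 0.26) and Pdk1 (1.12 ± 0.14) rose, and glycolysis had 5 of 19 up and 1 down (6 and 3 over the list alone). The counts up and down, with those adjusted over the list alone in parentheses, were 3 and 0 of 26 (3 and 0) for apoptosis regulators, including Casp4 (1.29 ± 0.27) and Bcl2 (1.02 ± 0.26), and 4 and 1 of 22 (4 and 1) for antioxidant genes. They were 2 and 2 of 18 (4 and 2) for fatty acid oxidation, 1 and 1 of 12 (1 and 1) for heat shock, 2 and 1 of 13 (3 and 3) for hypoxia. For exocytosis and secretory granules they were 4 and 4 of 22 (4 and 4), and Vgf, a granule protein precursor, rose by 3.23 ± 0.16. The hypoxia mean was 0.04 and its median -0.34, opposite in sign. Of the 23 genes fixed to be given in each comparison 11 passed, and the 12 others included Irs1 (-0.67 ± 0.20), Igf1r (0.27 ± 0.20), Txnip (0.97 ± 0.30), Cdkn1a (-0.01 ± 0.20), Egr1 (-0.83 ± 0.72), Fos (-0.65 ± 0.57) and Mki67 (1.47 ± 0.44).

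In total 2245 of 13369 genes differed between untreated Irs2-/- and untreated wild-type islets (limma adjusted p under 0.05), 1106 higher and 1139 lower, and 625 of them by 2-fold or more. Of 28 lists 18 passed limma's camera, 14 higher and 4 lower, and 0 did with an estimated correlation, where the smallest adjusted p was 0.252 (all 28 had been tested with the preset correlation of 0.01). The gene count was 912 and 652 without untreated wild-type replicates 1 and 2, 1329 without either treated wild-type array and 761 without untreated Irs2-/- replicate 1, and 367 (297 higher, 70 lower) without the 2 arrays with outlying marker levels. The naming rule asked for arrays without overlap among the largest differences, so the next count adds no separate support. The genes counted also include Tac1, Cartpt, Grp, Pdyn, Nmb and Mfap3l, chosen outside the rule after their values were seen. Each of them is also among those counted below as keeping their call. Of 78 genes named for this comparison as past the test, all 78 had both arrays of a genotype above both of the other. Of these, 49 kept their call in each of the 8 fits without 1 array (56 without untreated Irs2-/- replicate 1 or untreated wild-type replicate 2, the fewest).

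Treatment of Irs2-/- mice with tungstate, the subject of the study's title, was followed by lower levels of immune genes and of genes that were high without Irs2. Cxcl9, a chemokine that attracts T cells, fell by 3.50 ± 0.30 (limma adjusted p = 0.00626), from 8.49 ± 0.00 (SD) to 4.99 ± 0.59. That level and the 4.63 ± 0.48 of untreated wild-type islets both lie below 5.27, so the size of the decrease and the distance left to wild type are not exact. The chemokine genes Ccl5 (-3.10 ± 0.36) and Ccl8 (-2.35 ± 0.32) and the macrophage scavenger receptor gene Marco (-2.30 ± 0.24) fell too. Gast fell 4.99-fold (-2.32 ± 0.13, limma adjusted p = 0.00174) to 7.81 ± 0.06 and so stayed above wild type. The other 5 of the 10 lowest were Ptger3 (-3.06 ± 0.39), Csn3 (-2.75 ± 0.39), Sorcs1 (-2.74 ± 0.41), the peptide gene Spx (-2.33 ± 0.33) and the protease inhibitor gene Serpinb1a (-2.29 ± 0.35). The 3 genes that rose were the guidance receptor gene Robo2 (1.30 ± 0.18, limma adjusted p = 0.0328), Fam184b (1.12 ± 0.14) and the transcription factor gene Atf5 (0.82 ± 0.12). Fmn2 (1.06 ± 0.21) and Trpm5 (1.11 ± 0.32) had the next largest differences upward and did not pass.

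As groups, macrophage and antigen presentation markers were lower after tungstate, with all 18 members below 0. Past the test were 7 of them (17 adjusted over the list alone), such as Aif1 (-1.66 ± 0.15, limma adjusted p = 0.0063), C1qc (-1.28 ± 0.13), the protease gene Ctss (-1.22 ± 0.14) and Cd68 (-1.58 ± 0.18). The list mean was -1.34 (limma camera adjusted p = 1.55e-20, adjusted p = 0.24 with an estimated correlation). Cell cycle genes had a mean of -0.78 with 0 of 31 past limma's test (20 down and 2 up over the list alone). Mcm5 was -1.63 ± 0.28, Rrm2 -1.30 ± 0.24, Ube2c -1.67 ± 0.33 and the proliferation marker Mki67 -1.83 ± 0.44. Lymphocyte markers had a mean of -1.61 with 0 of 13 past limma's test (3 down over the list alone; Cd3g -2.71 ± 0.52, Cd3d -1.74 ± 0.38, Cd2 -2.25 ± 0.51). Among inflammatory genes Ccl5 fell (1 of 18, and 5 over the list alone; Saa3 was -1.83 ± 0.37). Among the dedifferentiation genes Gast did (1 of 15, and 3 over the list alone; Hk2 was -0.65 ± 0.11, Fbp2 -0.95 ± 0.26 and Aldh1a3 -0.66 ± 0.55). The limma camera adjusted p of these 4 lists, in the order named, was 2.19e-09, 2.38e-05, 2.96e-05 and 2.38e-05, and the adjusted p was 0.718, 0.718, 0.718 and 0.462 with an estimated correlation. Which cells of the islets carried the cell cycle and dedifferentiation genes was not told apart here either. With genes under the 60th percentile left out the lymphocyte call ended (mean -1.54). Without untreated Irs2-/- replicate 1 the cell cycle mean was -0.45. The inflammatory mean of -0.85 was -0.35 and -1.34 without untreated Irs2-/- replicates 1 and 2.

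Beta cell genes lay higher after tungstate as a list, but no member passed. Of 25 genes 21 were above 0, with a mean of 0.33 (limma camera adjusted p = 2.38e-05, adjusted p = 0.718 with an estimated correlation) and 0 past limma's test also over the list alone. That mean was 0.13 without treated Irs2-/- replicate 2 and 0.52 without replicate 1 of that group, so its size rests on which treated array is kept. Slc2a2 was 0.997 ± 0.36 (limma adjusted p = 0.297), Ucn3 0.98 ± 0.32, Slc30a8 0.79 ± 0.22, Glp1r 0.51 ± 0.34, Nkx6-1 0.44 ± 0.19 and Pdx1 0.35 ± 0.16, with the treated arrays of Slc2a2 spread widely (11.80 ± 0.89, SD). Ins2 (0.00 ± 0.10), Gcg (0.09 ± 0.12) and Sst (0.24 ± 0.13) did not pass. The list of other endocrine cells had 0 of 9 past limma's test (0 over the list alone) with a mean of 0.20 (0.061 and 0.35 without untreated Irs2-/- replicates 1 and 2, 0.060 and 0.35 without treated replicates 1 and 2). Of the 23 genes given in each comparison 0 passed limma's test, from -1.83 (Mki67) to 0.997 (Slc2a2), with Mt1 at 0.59 ± 0.20, Mt2 at 0.65 ± 0.25, Ddit3 at -0.61 ± 0.35, Txnip at -0.86 ± 0.30 and Egr1 at 0.32 ± 0.72.

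Among the remaining lists the limma camera adjusted p was 0.00421 for apoptosis regulators (mean -0.30; Casp1 -1.43 ± 0.35), 0.00414 for interferon response (mean -0.40; Psmb8 -1.22 ± 0.23, Gbp2 -1.77 ± 0.39). It was 0.0293 for fibroblast genes (mean -0.42; Thy1 -0.85 ± 0.37), 0.0293 for immediate early genes (mean -0.36; Dusp6 -1.06 ± 0.20, Phlda1 -0.63 ± 0.13), 0.0357 for other endocrine cells and 0.047 for ribosomal proteins (mean -0.11). With an estimated correlation the adjusted p lay between 0.721 and 0.753 for these 6 lists. The SE of the array means was 0.11, 0.22, 0.39, 0.49, 0.18 and 0.07 for the same lists, in the order named. In each of them 0 genes passed limma's test over all genes, and over the list alone 0, 4, 0, 3, 0 and 0 fell, in the same order. Members past the test outside these lists were Vgf (-1.32 ± 0.16), Pfkfb3 (-1.72 ± 0.26) and Pdk1 (-0.90 ± 0.14), while Edem1 (-0.80 ± 0.17), Scd2 (0.54 ± 0.11), Scd1 (-1.94 ± 0.44), Ramp2 (-0.77 ± 0.20) and Flt1 (0.48 ± 0.14) were not. The endothelial list did not pass (mean 0.09), and neither did the acinar list (mean -0.29). Without untreated Irs2-/- replicate 1 the immediate early mean turned to 0.29, and the calls of the apoptosis (-0.18), interferon (-0.21), fibroblast (-0.28), other endocrine (0.061) and ribosomal (-0.11) lists ended. The interferon (-0.20), fibroblast (-0.18) and ribosomal (-0.043) calls also ended without treated Irs2-/- replicate 2, the immediate early (-0.28) and other endocrine (0.060) calls without treated Irs2-/- replicate 1, and the ribosomal call without untreated Irs2-/- replicate 2 or either untreated wild-type array (-0.11 in each). Calls were kept with other means without untreated Irs2-/- replicate 2 (immediate early -1.01, other endocrine 0.35), treated Irs2-/- replicate 1 (fibroblast -0.66, interferon -0.61, ribosomal -0.17) and treated Irs2-/- replicate 2 (other endocrine 0.35). At the 60th percentile the immediate early (-0.28), apoptosis (-0.21) and ribosomal (-0.11) calls ended, with the mean of a gene's probe sets the apoptosis call (-0.22) and with the acinar covariate the other endocrine call (0.19). Without the 2 arrays with outlying marker levels the other endocrine (0.061) and ribosomal (-0.11) calls ended and the immediate early mean was 0.29.

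In total 66 genes changed with tungstate in Irs2-/- islets (limma adjusted p under 0.05), 3 higher and 63 lower, 52 of them by 2-fold or more, and 1780 of 13369 had an unadjusted p under 0.05. Of 28 lists 12 passed limma's camera, 2 higher and 10 lower, and 0 with an estimated correlation (smallest adjusted p = 0.24). The gene count was 16 without either treated wild-type array, 32 and 265 without untreated Irs2-/- replicates 1 and 2, and 137 and 29 without treated Irs2-/- replicates 1 and 2. It was 172 with the acinar covariate, 34 at the 60th percentile, 19 with only the arrays compared, 27 with array weights, 29 with all probe sets and 31 without the 2 arrays with outlying marker levels. The count with all probe sets is of probe sets, among more tested features than genes. Of the 22 genes named for this comparison as past the test, Aif1, Cxcl9, Gast, Mfap3l and Nmb kept their call in each of the 8 fits without 1 array. All 22 had non-overlapping arrays, which the naming rule asked of the largest differences. Nmb and Mfap3l were added outside the rule for this comparison, after their values were seen.

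**Figure D2:**
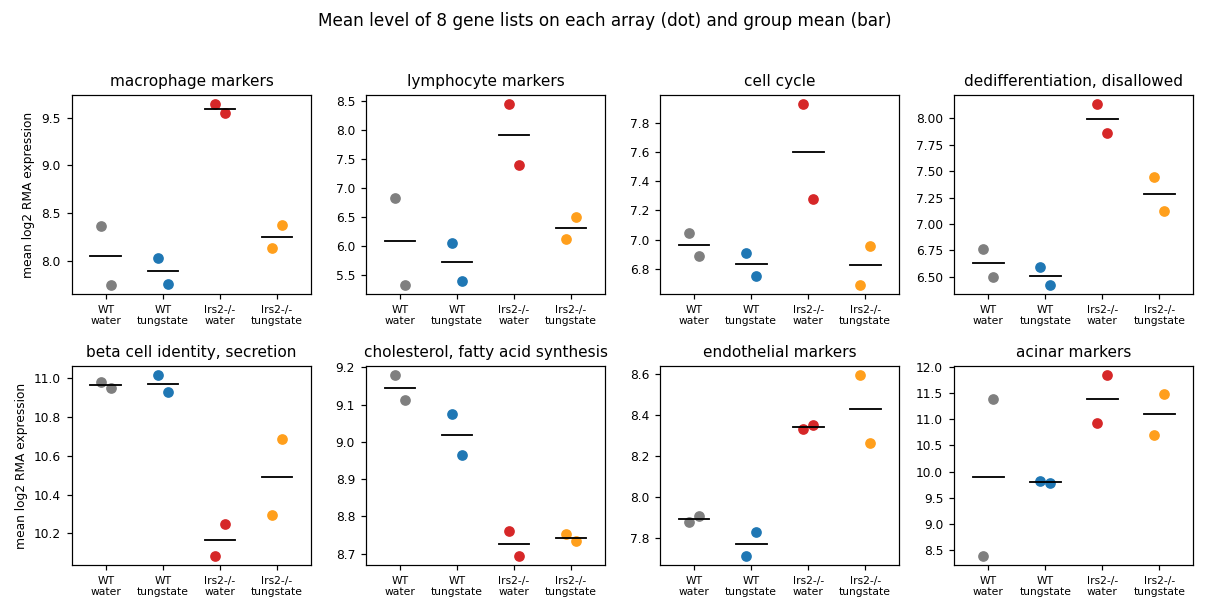
Mean log2 RMA expression of the tested members of 8 gene lists on each array (dots), with the mean of the 2 arrays of each group (bar). The macrophage list is highest on the untreated Irs2-/- arrays, the beta cell list is lowest there, and the acinar list differs by 3 log2 units between the untreated wild-type arrays.

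In wild-type islets tungstate changed 0 genes by limma's test, with 364 of 13369 at an unadjusted p under 0.05 and a smallest adjusted p of 0.796. Of the genes that fell in Irs2-/- islets, Gast was at 0.05 ± 0.13 and Cxcl9 at -0.00 ± 0.30. But both genes read below 5.27 in wild-type islets already without tungstate (4.61 and 4.63), so a decrease there may go unseen. That cut is a percentile of the probe sets and not a measured limit of detection. The list of fibroblast and stellate cell markers was lower, with all 19 members below 0, a mean of -0.90 and 0 past limma's test (5 down over the list alone; Col3a1 -1.94 ± 0.42, Lum -1.67 ± 0.43, Col1a2 -1.68 ± 0.45). The immediate early list had a mean of -0.45 and 0 of 23 past limma's test (1 down over the list alone; Phlda1 -0.60 ± 0.13, Spry4 -0.34 ± 0.12). The limma camera adjusted p was 5.22e-12 and 0.00292 for these 2 of 28 lists, and the adjusted p was 0.896 and 0.991 with an estimated correlation. With the SE of the array means the list means were -0.90 ± 0.39 and -0.45 ± 0.49. Differences that did not pass included Robo2 (0.76 ± 0.18), Nmnat2 (0.54 ± 0.16), Arid3b (0.52 ± 0.12) and Prph (0.50 ± 0.11) upward. Downward they included the collagen-binding gene Dcn (-2.62 ± 0.76), Gdf10 (-1.94 ± 0.50), the heat shock gene Hspa1b (-1.93 ± 0.53) and Abca8a (-1.83 ± 0.49). The 23 genes given in each comparison ran from -1.01 (Egr1) to 0.19 (Aldh1a3) with 0 past limma's test. With the acinar level as a covariate 9 genes passed, all lower, and without untreated wild-type replicate 2 the count was also 9. Without treated wild-type replicate 2 the immediate early call ended (mean -0.23). The fibroblast mean was -0.43 and -1.37 without untreated wild-type replicates 1 and 2.

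The comparison of the genotypes among treated mice shows what separated Irs2-/- from wild-type islets under tungstate. Among the 10 highest genes Tac1, the precursor of substance P, was higher by 3.28 ± 0.46 (limma adjusted p = 0.0271), Cartpt by 3.15 ± 0.40, Gast by 3.15 ± 0.13 (limma adjusted p = 0.000164) and Grp, gastrin-releasing peptide, by 3.10 ± 0.52. 6330403K07Rik (3.07 ± 0.41), the water channel gene Aqp1 (3.05 ± 0.36), Slc38a5 (2.91 ± 0.37), Csn3 (2.86 ± 0.39), the collagen gene Col3a1 (2.61 ± 0.42) and the endothelial gene Vwf (2.50 ± 0.32) completed the 10 highest. Besides Irs2 (-2.93 ± 0.16), Dpp10 (-2.50 ± 0.29), Pcdh15 (-1.92 ± 0.24), Aard (-1.89 ± 0.27), Prss53 (-1.86 ± 0.24), Ly6h (-1.82 ± 0.20), Kcnj12 (-1.46 ± 0.24) and Sst (-1.14 ± 0.13) were among the genes that were lower. Gast read below 5.27 in treated wild-type islets and Irs2 in treated Irs2-/- islets, so the sizes of these differences are not exact. Endothelial markers were higher as a list (mean 0.66; 3 of 14 rose, Ptprb by 0.90 ± 0.13, Tek by 1.15 ± 0.18 and Plvap by 0.85 ± 0.14; 12 over the list alone). So were fibroblast markers (mean 1.26; Col3a1 alone of 19 rose, 14 up and 1 down over the list alone; Col1a2 2.36 ± 0.45, Lum 2.21 ± 0.43). Beta cell genes were lower (mean -0.48; 0 of 25 past limma's test, 10 down and 1 up over the list alone), with Trpm5 at -1.68 ± 0.32, Slc2a2 at -1.33 ± 0.36, Ucn3 at -1.18 ± 0.32, Glp1r at -1.45 ± 0.34 and Nkx6-1 at -0.82 ± 0.19. Cholesterol genes were lower (mean -0.28; Scd2 fell by 0.72 ± 0.11, 1 of 21, and 3 over the list alone; Elovl6 -0.79 ± 0.14) and dedifferentiation genes higher (mean 0.78; Gast alone of 15 rose, 3 over the list alone; Aldh1a3 2.10 ± 0.55). The limma camera adjusted p of these 5 lists, in the order named, was 1.53e-11, 3.86e-11, 1.87e-05, 4.47e-05 and 2.23e-05, and the adjusted p was 0.305, 0.411, 0.444, 0.305 and 0.305 with an estimated correlation. Without treated Irs2-/- replicate 1 the beta cell mean was -0.28.

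In that comparison 137 genes differed (limma adjusted p under 0.05), 85 higher and 52 lower, and 2147 had an unadjusted p under 0.05. Of those called in untreated mice in the same direction, 71 of the 85 and 48 of the 52 were shared, where independent lists of these sizes would share 7.03 and 4.43. Of 28 lists 15 passed limma's camera (smallest adjusted p = 0.305 with an estimated correlation, 0 lists past). The 10 not named so far were the acinar, Reg, duct, macrophage, immediate early, inflammatory, interferon and ribosomal lists, higher, and the insulin and IGF and metallothionein lists, lower. The insulin and IGF list includes Irs2 itself, whose loss lowers the list mean by design, and it was not tested without Irs2. Of the macrophage markers 0 of 18 passed limma's test (0 over the list alone), with a mean of 0.36. The gene count was 3 and 4 without treated wild-type replicates 1 and 2, 69 without either untreated Irs2-/- array, and 18 and 679 without treated Irs2-/- replicates 1 and 2. It was 280 (237 higher, 43 lower) with the acinar covariate, 224 with trend and robust moderation and 77 with the mean of a gene's probe sets. With all probe sets 81 passed, a count of probe sets among more tested features than genes. Of the 22 genes named for this comparison as past the test, only Gast and Irs2 kept their call in each of the 8 fits without 1 array. Without either treated wild-type array 19 of the 22 lost it, and without treated Irs2-/- replicate 1 16 did. Without treated Irs2-/- replicate 2 the macrophage call ended (mean 0.24), as did the inflammatory (0.29), insulin and IGF (-0.13) and metallothionein (-0.30) calls, and without treated Irs2-/- replicate 1 the interferon (0.083) and metallothionein (-0.29) calls. Without treated wild-type replicate 2 the inflammatory (0.29), insulin and IGF (-0.18), interferon (0.25) and metallothionein (-0.21) calls ended, and the macrophage and immediate early means were 0.23 and 0.25 (0.46 with it). The duct mean of 0.57 was 0.26 and 0.89 without treated Irs2-/- replicates 1 and 2, the ribosomal mean of 0.16 was 0.093 without the first and the interferon mean of 0.29 was 0.49 without the second. At the 60th percentile the inflammatory (0.36) and interferon (0.21) calls ended, with the mean of a gene's probe sets the metallothionein call (-0.25) and with the acinar covariate the insulin and IGF call (-0.11).

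Treated Irs2-/- islets were also set against untreated wild-type islets, to see what was left of the genotype difference. The largest differences upward were in Tac1 (4.05 ± 0.46, limma adjusted p = 0.021), Grp (3.51 ± 0.52), Cartpt (3.47 ± 0.40) and Gast (3.20 ± 0.13, limma adjusted p = 0.000145). Others were Csn3 (2.94 ± 0.39), Slc38a5 (2.61 ± 0.37), Aass (2.35 ± 0.20) and the opioid precursor gene Pdyn (2.23 ± 0.30). Lower were Irs2 (-3.00 ± 0.16), Dpp10 (-2.62 ± 0.29), Pcdh15 (-2.15 ± 0.24), Aard (-2.06 ± 0.27), Pacc1 (-1.54 ± 0.20), Ly6h (-1.42 ± 0.20), Stxbp5l (-1.26 ± 0.14), Hspa12a (-1.25 ± 0.18), Sst (-1.11 ± 0.13) and, in lipid synthesis, Scd2 (-1.03 ± 0.11). Gast and Csn3 read below 5.27 in untreated wild-type islets, and Irs2 in treated Irs2-/- islets, so these differences are not exact measures of size. Slc2a2 (-1.31 ± 0.36) and Trpm5 (-1.47 ± 0.32) did not pass. The beta cell list was lower (mean -0.47; 0 of 25 past limma's test, 12 down over the list alone), and so was the cholesterol list (mean -0.40; 1 of 21 fell, 7 over the list alone). The endothelial list was higher (mean 0.54; 0 of 14 past limma's test, 11 up over the list alone; Ptprb 0.75 ± 0.13). The limma camera adjusted p was 0.000151, 1.72e-06 and 7.71e-09, and the adjusted p was 0.613, 0.397 and 0.397 with an estimated correlation. The macrophage list was 0.20 higher, with 0 of 18 past limma's test (0 over the list alone; limma camera adjusted p = 0.0196, adjusted p = 0.693 with an estimated correlation). Without treated Irs2-/- replicate 1 the beta cell mean was -0.28 and the macrophage mean 0.32. The macrophage mean was 0.51 and -0.11 without untreated wild-type replicates 1 and 2, and without treated Irs2-/- replicate 2 it was 0.080 and its call ended.

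By limma 47 genes differed in that comparison, 26 higher and 21 lower, with 2489 at an unadjusted p under 0.05. Of 28 lists 14 passed limma's camera, 9 higher and 5 lower, and 0 with an estimated correlation (smallest adjusted p = 0.397). The gene count was 4 and 12 without untreated wild-type replicates 1 and 2, 9 without either treated wild-type array, 22 without either untreated Irs2-/- array, and 7 and 585 without treated Irs2-/- replicates 1 and 2. The balance of directions moved with the setting: with each array centred on its median 87 passed, 27 higher and 60 lower, and with trend and robust moderation 142, 54 higher and 88 lower. With only the arrays compared 8 passed, and 5 without the 2 arrays with outlying marker levels. Of the 18 genes named here as past the test, only Gast and Irs2 kept their call in all fits without 1 array. Without untreated wild-type replicate 2 the macrophage mean turned to -0.11 and the fibroblast mean from 0.35 to -0.12, and without untreated wild-type replicate 1 the acinar mean turned from 1.21 to -0.29. Macrophage (0.080), insulin and IGF (-0.21), metallothionein (-0.33) and amino acid (-0.34) calls ended without treated Irs2-/- replicate 2, and duct (0.13), fibroblast (0.12), oxidative phosphorylation (0.066), metallothionein (-0.31) and amino acid (-0.22) calls without treated Irs2-/- replicate 1. Without untreated wild-type replicate 1 the insulin and IGF (-0.20) and oxidative phosphorylation (0.077) calls ended, and without replicate 2 of that group the amino acid call (-0.23). The acinar mean was 2.71 without untreated wild-type replicate 2. The fibroblast mean was 0.82 without untreated wild-type replicate 1 and 0.59 without treated Irs2-/- replicate 2, and the duct mean of 0.45 was 0.76 without the latter. The amino acid call also ended with no filter (-0.095) and at the 60th percentile (-0.28), and the metallothionein call at the 60th percentile (-0.32), with the mean of a gene's probe sets (-0.28) and without the 2 arrays with outlying marker levels (-0.23). The insulin and IGF call, which includes the loss of Irs2 itself, ended with the mean of a gene's probe sets (-0.22), with the acinar covariate (-0.20) and without those 2 arrays (-0.20). The oxidative phosphorylation call ended with the covariate (0.071) and without those 2 arrays (0.077), where the acinar mean was -0.29.

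The difference between the tungstate responses of the genotypes was tested as an interaction. By limma 3 genes passed, all with a larger decrease in Irs2-/- islets: Gast (-2.37 ± 0.19, adjusted p = 0.021), Nmb, a bombesin-like peptide (-2.09 ± 0.20, adjusted p = 0.0263), and Mfap3l (-2.01 ± 0.18, adjusted p = 0.0263). In untreated wild-type islets Gast (4.61) and Cxcl9 (4.63) read below 5.27 and Nmb (5.52) and Mfap3l little above it. A decrease there may have had little or no room to appear, so these interactions do not show that tungstate acts otherwise in wild-type islets. In this test 862 genes had an unadjusted p under 0.05. Cxcl9 (-3.50 ± 0.43, limma adjusted p = 0.092), Csn3 (-2.83 ± 0.55), Aif1 (-1.52 ± 0.21) and C1qc (-1.26 ± 0.19) did not pass. Of 28 lists 16 passed limma's camera, 7 higher and 9 lower, led by macrophage genes (mean -1.18; 0 of 18 past limma's test, 12 down over the list alone; camera adjusted p = 5.22e-20, adjusted p = 0.251 with an estimated correlation), and 0 passed with an estimated correlation. The gene count was 0 without either untreated wild-type array, either treated wild-type array or untreated Irs2-/- replicate 2, 10 without untreated Irs2-/- replicate 1, and 12 and 5 without treated Irs2-/- replicates 1 and 2. It was 6 without the 2 arrays with outlying marker levels and 0 with all probe sets. Gast, Nmb and Mfap3l all kept their call without untreated Irs2-/- replicate 1 or treated Irs2-/- replicate 1, 2 of them without treated Irs2-/- replicate 2, and 0 without any of the other arrays. The calls of 13 of the 16 lists ended without at least 1 of the arrays.

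Averaged over treatment, 4 arrays against 4, 2950 genes differed by genotype in limma's test, 1459 higher and 1491 lower. Every array of a genotype lay beyond the 4 of the other for Irs2 (-3.02 ± 0.11), Gast (4.33 ± 0.09, limma adjusted p = 8.89e-07), Csn3 (4.27 ± 0.27), the Reg gene Reg3b (4.54 ± 0.99), Cidea (3.34 ± 0.40), Grp (3.19 ± 0.37) and Tac1 (3.12 ± 0.33). The same held for Gad1 (-2.95 ± 0.41), Cox6a2 (-2.86 ± 0.46) and Dpp10 (-2.54 ± 0.21). Of 28 lists 19 passed limma's camera, 15 higher and 4 lower, and 0 with an estimated correlation (smallest adjusted p = 0.256). The gene count was 1389 and 1427 without treated wild-type replicates 1 and 2 and 1905 without untreated wild-type replicate 2, and 1680 with the acinar covariate (1092 higher, 588 lower), 1395 without the 2 arrays with outlying marker levels and 4512 with all probe sets. The count with all probe sets is of probe sets, among more tested features than genes, and is not a like count. Averaged over genotype, tungstate changed 12 genes in limma's test, 1 higher and 11 lower, among them Gast (-1.14 ± 0.09) and Aif1 (-0.90 ± 0.10), with 1459 at an unadjusted p under 0.05. The tungstate difference of Gast was -2.32 in Irs2-/- and 0.05 in wild-type islets, so its average describes neither genotype. Of 28 lists 10 passed limma's camera, 1 higher and 9 lower, and 0 with an estimated correlation (smallest adjusted p = 0.34). That count was 0 without untreated wild-type replicate 1 or either treated wild-type array, 50 without untreated wild-type replicate 2, 7 and 76 without untreated Irs2-/- replicates 1 and 2, and 22 and 6 without treated Irs2-/- replicates 1 and 2. It was 90 with the acinar covariate, 7 with the mean of a gene's probe sets, 5 with the replicate number as a block, 4 with array weights, 3 with quantile normalization and 0 with all probe sets.

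The tungstate differences in Irs2-/- islets ran opposite to the genotype differences. Of the 66 genes called for tungstate, 62 were called higher without Irs2 and lower after tungstate, such as Gast, Cxcl9 and Aif1, and 3 were called lower and then higher, where independent lists of these sizes would share 5.21 and 0.256. Of the 2245 genes called for genotype, 95.3% moved back toward wild type after tungstate, by any amount. Across the tested genes, which are not independent replicates, Pearson's r between both differences was -0.79 and the covariance -0.15. The untreated Irs2-/- arrays enter both differences with opposite signs, and in 100 simulations with no effect r was -0.50 and the covariance -0.018. In 100 simulations with the genotype effect and no tungstate effect, 55.0% of the genes moved back (52.1 to 57.6) and 0.19 genes on average were shared in opposite directions. The covariance exceeded the simulated one by -0.13. The simulated noise was independent between genes and alike in all groups. The simulated values and ranges therefore do not cover genes that vary together or groups of unequal spread. With a different untreated Irs2-/- array in each difference r was -0.66 and -0.48, and the covariance averaged -0.12. Part of the excess may still come from what those arrays share. The tungstate differences in the 2 genotypes, which share no arrays, had r = 0.30 across genes, with -0.03 without untreated wild-type replicate 1, 0.14 without treated wild-type replicate 2 and 0.19 without untreated Irs2-/- replicate 1.

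**Figure D3:**
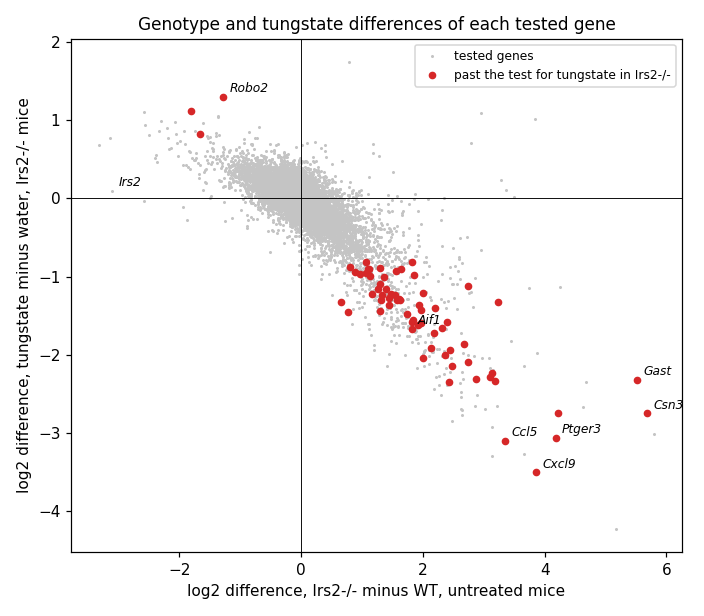
Each dot is 1 of 13369 tested genes, with the log2 difference between untreated Irs2-/- and untreated wild-type islets on the horizontal axis and that between treated and untreated Irs2-/- islets on the vertical axis. The 66 genes past limma's test for tungstate (red) lie mostly at the lower right, and both axes share the untreated Irs2-/- arrays, which alone give a negative slope.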

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

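The tests of explanations in the last 3 paragraphs were chosen only after the results were seen, while the tests of a difference between the genotypes were planned. Tungstate differences that differed between Irs2-/- and wild-type islets in limma's interaction test were those of Gast (-2.37 ± 0.19 SE, adjusted p = 0.021; -2.32 in Irs2-/- and 0.05 in wild-type islets), Mfap3l (-2.01 ± 0.18, adjusted p = 0.0263; -1.94 and 0.06) and Nmb (-2.09 ± 0.20, adjusted p = 0.0263; -1.92 and 0.17). In untreated wild-type islets Gast read 4.61, below the 5.27 under which genes were left out, and Nmb (5.52) and Mfap3l little above it. A decrease there may have had little or no room to appear, so a different action of tungstate in the genotypes is not shown. None of these 3 calls held in each fit without 1 array: 0 of them passed without either untreated or either treated wild-type array or without untreated Irs2-/- replicate 2, and 2 passed without treated Irs2-/- replicate 2.

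Of the gene lists, 16 differed between the genotypes in their response to tungstate by limma's camera, and 0 did with an estimated correlation (smallest adjusted p = 0.251). Mean interaction ± SE of the array means was -1.18 ± 0.36 for macrophage, -1.25 ± 0.995 for lymphocyte, -0.64 ± 0.37 for cell cycle, -0.59 ± 0.26 for dedifferentiation, -0.56 ± 0.52 for inflammatory, -0.31 ± 0.32 for interferon, -0.20 ± 0.13 for glycolysis, -0.12 ± 0.12 for oxidative phosphorylation and -0.099 ± 0.098 for ribosomal genes. It was 0.48 ± 0.55 for fibroblast, 0.34 ± 0.38 for heat shock, 0.32 ± 0.22 for beta cell, 0.25 ± 0.25 for other endocrine, 0.21 ± 0.18 for endothelial, 0.21 ± 0.12 for amino acid and serotonin, and 0.14 ± 0.073 for cholesterol genes. Macrophage, lymphocyte and cell cycle lists kept the camera call in each fit without 1 array, and the other 13 did not. At the 60th percentile, though, the lymphocyte call ended (-0.97), as did that of glycolysis (-0.094). With no filter on the mean the amino acid and serotonin mean was 0.020 and its call ended. Without the 2 arrays with outlying marker levels the fibroblast (0.15) and inflammatory (-0.14) calls ended and the mean of other endocrine genes was -0.0044. The calls that ended without untreated wild-type replicate 1 were other endocrine (0.14), fibroblast (0.012), oxidative phosphorylation (-0.084) and heat shock (0.33), and without replicate 2 glycolysis (-0.093), interferon (-0.17), ribosomal (-0.043) and amino acid (0.16). Without treated wild-type replicate 1 they were endothelial (0.15), fibroblast (0.39), glycolysis (-0.17), heat shock (0.17) and ribosomal (-0.049), and without replicate 2 other endocrine (0.14) and amino acid (0.12). Without untreated Irs2-/- replicate 1 they were other endocrine (0.10), glycolysis (-0.14), inflammatory (-0.066), interferon (-0.12), ribosomal (-0.10) and amino acid (0.20). Without replicate 2 of that group they were fibroblast (0.34), oxidative phosphorylation (-0.0070), cholesterol (0.11), heat shock (0.073), ribosomal (-0.096) and amino acid (0.23). Without treated Irs2-/- replicate 1 they were other endocrine (0.10), endothelial (0.041), fibroblast (0.25), glycolysis (-0.24), cholesterol (0.13), heat shock (0.12) and amino acid (0.27). Without replicate 2 of that group they were beta cell (0.12), dedifferentiation (-0.43), glycolysis (-0.16), oxidative phosphorylation (-0.074), interferon (-0.11), ribosomal (-0.034) and amino acid (0.15). Of the means whose call was kept, those that moved by more than 1.5 times were lymphocyte -2.01, glycolysis -0.31 and ribosomal -0.15 without untreated wild-type replicate 1, and lymphocyte -0.50 and fibroblast 0.95 without replicate 2. Without treated wild-type replicate 2 they were cholesterol 0.087, heat shock 0.50 and ribosomal -0.15. Without untreated Irs2-/- replicate 1 they were lymphocyte -0.73, cell cycle -0.32, oxidative phosphorylation -0.22 and heat shock 0.60, and without replicate 2 other endocrine 0.39, cell cycle -0.97, inflammatory -1.05 and interferon -0.51. Without treated Irs2-/- replicate 1 they were beta cell 0.52, interferon -0.51 and ribosomal -0.16, and without replicate 2 other endocrine 0.39, endothelial 0.37 and heat shock 0.56.

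Probe sets that name no single gene were outside the comparisons of the report. Of 3818 tested, 65 were higher and 81 lower in untreated Irs2-/- than in untreated wild-type islets by limma, and 0 passed for tungstate in Irs2-/- islets, tungstate in wild-type islets and the genotypes in treated mice (499, 187 and 290 at an unadjusted p under 0.05).

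Macrophage and lymphocyte markers were lower after tungstate in Irs2-/- islets. A smaller share of all non-endocrine tissue would lower endothelial, fibroblast, acinar and duct genes alike. The endothelial list lay above the macrophage list by 1.43 ± 0.34 in this comparison, which argues against it as the whole cause, while the fibroblast (-0.42 ± 0.39), acinar (-0.29 ± 1.14) and duct (-0.021 ± 0.22) means do not exclude some loss of such tissue. With the acinar level as a covariate the macrophage mean was -1.39 ± 0.20, against -1.34 without it. The acinar mean itself differed little here, so only a steep slope could have removed the macrophage difference. That slope rests mainly on the untreated wild-type arrays, whose acinar levels were 8.39 and 11.39. This fit therefore does not decide on exocrine RNA. Fewer immune cells and lower expression per immune cell may each give this pattern and were not separated. A preparation effect shared by both untreated Irs2-/- arrays was not tested and stays open. Their 18S signal (10.84 ± 0.30, SD) and 3' minus 5' differences of Gapdh (0.39 ± 0.03) and actin (0.83 ± 0.15) were the lowest group means. Both arrays lay below every other array on each measure, though close to the nearest.

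Beta cell genes were lower in untreated Irs2-/- islets. Dilution by other cells would lower secretory granule genes alike, but their list lay above the beta cell list by 0.93 ± 0.19, although its members went both ways (SD 0.85, with 3 of 22 under the beta cell median). With the acinar level as a covariate the beta cell mean was -0.85 ± 0.21, against -0.80 without it. The slope of that fit rests mainly on the untreated wild-type arrays, which limits what it can show. Granule genes that went both ways do not exclude some dilution. Lower expression per beta cell and a smaller share of beta cells among endocrine cells may each be the source and were not separated. A preparation effect shared by the untreated Irs2-/- arrays stays open here too.

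Tungstate differences ran opposite to genotype differences in Irs2-/- islets. The arrays that both comparisons share give a negative r by themselves, but with a different untreated Irs2-/- array in each comparison r averaged -0.57 across genes (-0.66 and -0.48), which argues against shared arrays as the whole cause. A treatment that moves expression toward wild type may be the source, as a hypothesis. Something that sets both untreated Irs2-/- arrays apart from the others, such as a shared preparation, would give the same pattern and was not excluded.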

How the results depend on the processing

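Leaving out 2 arrays with outlying marker levels (untreated wild-type replicate 1, untreated Irs2-/- replicate 1) was an alternative chosen after seeing the data, and the others were planned. Among 242 gene results under other settings, 4555 of 5249 values kept their side of the threshold, 581 were weaker, 113 stronger and 0 reversed. A change of sign counted as reversed only where the gene passed in the main fit or in the other. Genes that passed in neither may have changed sign within the 4555. Among 106 list results, 1425 of 1578 kept direction and side of the threshold, 143 were weaker and 10 reversed. The estimated correlation is not among these and left 0 lists in all 8 contrasts. Where 1 array is left in a group it is assumed to vary like the other groups. Fitting only the arrays compared gives no value for the interaction and the averaged contrasts, which use all 8 arrays, and the acinar list has none with the acinar covariate. Array weights came out equal within each group of 2, so they weigh groups and not single arrays. RMA values near the top of the scale, such as Ins2, limit what can be seen, as do dim probe sets.

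Without 1 array, in turn, the gene count ranged from 652 to 2639 for genotype untreated, 16 to 265 for tungstate in Irs2-/-, 0 to 9 for tungstate in wild type, 3 to 679 for genotype treated, 4 to 585 for treated Irs2-/- against untreated wild type, 0 to 12 for the interaction, 1389 to 3013 for genotype averaged and 0 to 76 for tungstate averaged. The lists ranged from 17 to 21, 9 to 12, 2 to 8, 12 to 17, 11 to 16, 9 to 15, 16 to 20 and 8 to 14 in the same order. The reversal r ranged from -0.83 to -0.64 and the agreement of the tungstate differences from -0.027 to 0.39. List means that turned ranged from -0.0038 to 2.99 (acinar) and -0.27 to 1.03 (immediate early) for genotype untreated, from -1.01 to 0.29 (immediate early) for tungstate in Irs2-/-, and from -0.29 to 2.71 (acinar), -0.11 to 0.51 (macrophage) and -0.12 to 0.82 (fibroblast) for treated Irs2-/- against untreated wild type. Fewer arrays also leave fewer degrees of freedom. The spread is pooled over the 4 groups, and treated wild-type arrays varied least. Across genes the SD of the difference between both arrays of a group was 0.21 there. It was 0.35 for untreated wild-type, 0.34 for untreated Irs2-/- and 0.34 for treated Irs2-/- islets. Limma p-values among Irs2-/- islets thus borrow a smaller spread and may be too small. Leaving out a treated wild-type array changes this spread but not the tungstate difference in Irs2-/- islets. The cause of each change was not tested further.

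By setting, the counts that moved were as follows, and the cause was not tested. With no filter 7 lists passed for tungstate in wild type. At the 60th percentile 34 genes passed for tungstate in Irs2-/-. With trend and robust moderation 224 passed for genotype treated and 142 for treated Irs2-/- against untreated wild type. With only the arrays compared 19 passed for tungstate in Irs2-/- and 8 for treated Irs2-/- against untreated wild type, in a fit with fewer samples. With the replicate number as a block 5 passed for tungstate averaged; the differences between replicates 1 and 2 of a group correlated with those of another group at r of -0.07 to 0.42, and the number pairs no samples in the labels. With array weights 27 passed for tungstate in Irs2-/- and 4 for tungstate averaged. With median centring 87 passed for treated Irs2-/- against untreated wild type (27 higher, 60 lower), and with quantile normalization 3 for tungstate averaged. With the mean of a gene's probe sets 5 lists passed for tungstate in wild type, 77 genes for genotype treated and 7 for tungstate averaged. With all probe sets the counts are of probe sets, among more tested features than genes, and are not like counts. By limma 29 probe sets passed for tungstate in Irs2-/-, 81 for genotype treated, 0 for the interaction, 4512 for genotype averaged and 0 for tungstate averaged. With the acinar covariate 172 passed for tungstate in Irs2-/-, 9 for tungstate in wild type, 280 for genotype treated, 1680 for genotype averaged and 90 for tungstate averaged.

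At an adjusted p under 0.1, a looser threshold, the counts were 3511 for genotype untreated, 153 for tungstate in Irs2-/-, 516 for genotype treated, 463 for treated Irs2-/- against untreated wild type, 13 for the interaction and 24 for tungstate averaged. At 2-fold or more, a stricter one, they were 625 for genotype untreated, 80 for genotype treated, 427 for genotype averaged and 4 for tungstate averaged. Without the 2 arrays with outlying marker levels 367 genes passed for genotype untreated, 31 for tungstate in Irs2-/-, 5 for treated Irs2-/- against untreated wild type, 6 for the interaction and 1395 for genotype averaged, 7 lists passed for tungstate in wild type, and the agreement r was 0.036. In that setting the immediate early mean was -0.17 for genotype untreated and 0.29 for tungstate in Irs2-/-, the acinar mean -0.29 for treated Irs2-/- against untreated wild type, and the mean of other endocrine genes -0.0044 for the interaction, all reversed.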

Other observations

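The genes compared, the permutation and the splits in this part were chosen only after the results were seen, while the contrasts and limma's tests were planned. Some single genes that were higher without Irs2 passed the tungstate test in Irs2-/- islets and others did not. They were not tested as a group. Tac1, the precursor of substance P, was 2.96 ± 0.46 (SE) higher in untreated Irs2-/- than in wild-type islets (limma adjusted p = 0.00787) and stood at 9.85 ± 0.39 (SD) after tungstate against 8.76 ± 1.07 before. Cartpt (3.36 ± 0.40), Grp (3.28 ± 0.52) and the opioid precursor gene Pdyn (2.72 ± 0.30) were higher without Irs2 as well, and their tungstate differences of 0.11 ± 0.40, 0.23 ± 0.52 and -0.49 ± 0.30 did not pass, as that of Tac1 did not (1.09 ± 0.46). Vgf (3.23 ± 0.16), Nmb (2.13 ± 0.14) and Mfap3l (2.45 ± 0.13) were also higher without Irs2 and fell after tungstate (-1.32 ± 0.16, -1.92 ± 0.14 and -1.94 ± 0.13, limma adjusted p = 0.0185, 0.00369 and 0.00247).

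How far tungstate left macrophage and beta cell genes from wild type was not settled. Macrophage genes past the genotype test upward and beta cell genes past it downward were compared, so the beta cell gene that rose was left out. The median share of the genotype difference that was left was 15.1% for 16 macrophage genes (-5.78 to 58.6) and 57.9% for 14 beta cell genes (47.4 to 74.6). The medians differed by 42.7 percentage points (two-sided permutation of genes between the lists, p = 0.00025, 100000 permutations). Without treated Irs2-/- replicate 1 the difference was 16.5 points (35.9% for beta cell and 19.5% for macrophage genes), and without treated replicate 2 it was 72.5 (80.9% and 8.32%). Genes of a list share these arrays, so this p may be too small, and the 2 treated arrays differ too much to size a difference between immune and beta cell genes.

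The 8 arrays can be split into 4 and 4 in 35 ways, counting the real split. By genotype 2559 genes passed in a fit of 2 groups, against at most 1 in any other split. So 1 of 35 gave as many, the lowest share these splits can give. The other splits mix the genotypes and leave that difference in their residual, so they are no clean measure of chance. Anything else that differs between the arrays of the genotypes, such as their preparation, was not excluded. By genotype 20 lists passed limma's camera with the preset correlation (highest other 17, 1 of 35). With an estimated correlation 0 passed in any of the 35 splits, so the lists do not exclude chance. By tungstate 0 genes passed limma's test (495 at an unadjusted p under 0.05), a count that all 35 splits reach whatever the data, so it says nothing about chance. There 9 lists passed with the preset correlation, which 22 of 35 splits reached, so chance cannot be excluded for these lists in this fit, which leaves the genotype difference in its residual. The highest of the other splits there, 2559 genes and 20 lists, is the genotype split, which points to genotype as the main structure of the arrays. This fit of 2 groups differs from the fit of 4 groups, which called 12 genes for tungstate averaged over genotype.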
